A study of Rattus norvegicus with 4 samples.

How the data were processed

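Gene expression was measured in cultured aortic smooth muscle cells of Sprague-Dawley rats on 4 Affymetrix rat expression arrays, each carrying 31099 probe sets. Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared by the standard Affymetrix protocol. The deposited values are linear probe set intensities, made with MAS5 per the submitters' processing notes; the MAS5 version and its scaling target are not given in the sources used here. All 4 columns had the same median intensity, 53.3, so the arrays as deposited shared a common median. Detection calls and scanner files were not used here, so whether a probe set was above background had to be judged from its intensity. Each array was assigned to its group from its title in the labels.

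Every array was rescaled to the same mean after the lowest and highest 2% of probe sets were trimmed, which multiplied the deposited values by 1.03 for the IL-1b vehicle, 1.01 for IL-1b, 1.01 for the PDGF-DD vehicle and 0.951 for PDGF-DD. Values under a floor, the 40th percentile of all probe sets pooled over the 4 arrays (intensity 28.1), were set to the floor. The floor was checked against probe sets that should be dark: 26 of 32 genes restricted to other organs and 27 of 27 unspiked bacterial control probe sets were at the floor on all 4 arrays. Probe sets were named from a platform annotation of 2016, in which 20832 probe sets had 1 gene symbol, 436 had several and 9831 were not listed; of those with 1 symbol, 20764 matched a gene of the GRCr8 RefSeq table by gene identifier, and no symbol changed. Probe sets with several symbols or none named no gene. For each of 14217 genes the probe set with the highest mean log2 intensity stood for the gene; 4525 genes had more than 1 probe set, and 10884 genes were above the floor on at least 1 array. Positions in the genome are not reported, because the annotation was used for names only.

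With 1 array per group there are no replicates, so no test was run and no p-value or standard deviation is given. Differences were described by a fixed rule of size, at least 2-fold, among genes above the floor on at least 1 of the arrays compared. Where a gene was at the floor on 1 array, its fold is a lower bound and is written as at least that fold. The comparisons were IL-1b against its vehicle, PDGF-DD against its vehicle, the vehicle arrays against each other as the background measured the same way, and the log2 ratio of IL-1b minus that of PDGF-DD. For each of 29 gene lists, the median log2 ratio of the measured members was set beside the medians of 10000 random lists of the same size, matched on mean intensity in 20 bins; the resulting percentile describes these arrays and is not a test of the conditions. The lists cover the contractile apparatus, vasoactive receptors, NF-kappaB targets, chemokines, cytokines, complement and acute phase genes, prostanoid and nitric oxide synthesis, interferon-stimulated genes, antigen presentation, proteases, protease inhibitors, extracellular matrix, the cell cycle (3 lists), growth factor feedback genes, PDGF and TGF-beta family genes, sterol and fatty acid synthesis, lipid uptake, glycolysis, oxidative stress, endoplasmic reticulum stress, osteochondrogenic genes, markers of other cell types (4 lists), genes of other organs and reference genes. Some genes stand in more than 1 list.

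Genes were named by a fixed rule. Per factor it takes the 8 highest and 8 lowest log2 ratios among genes above the floor on both arrays, and up to 4 in each direction among genes at the floor on 1 array. Each of these had to differ in the same direction by at least 2-fold from the other vehicle array. Its absolute log2 ratio also had to exceed the vehicle limit. This limit is the 99th percentile of the absolute log2 ratio between the vehicle arrays at the same intensity. Unnamed gene models were left out. The rule adds up to 4 members per list with the largest absolute ratio. It also adds 9 genes of prior interest (Acta2, Myh11, Tagln, Cnn1, Myocd, Klf4, Il1r1, Pdgfra and Pdgfrb). Further additions are the 6 largest and 6 smallest differences between the factors, and up to 8 genes at least 2-fold in opposite directions. Added genes did not have to differ from the other vehicle array or exceed the vehicle limit, and several named below do not. The text gives part of the genes this rule yields. Ccl2, Mki67, Jun, Egr1, Mmp2, Col1a1 and Col3a1 fall outside the rule and were chosen after their values were seen. The groups, comparisons, gene lists, naming rule and alternative settings, other than the scaling as deposited, were set before the data were examined.

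The steps were tested on simulated data in which 200 of 10388 genes were changed. The simulated pair stood for IL-1b against its vehicle but was built from the vehicle arrays. With noise drawn from the differences between the vehicle arrays, the 2-fold rule recovered 36.4% of simulated 2-fold changes. It recovered 94.7% of 4-fold and 91.4% of 8-fold changes, and called 9.2% of unchanged genes. That share follows from the distance between the vehicle arrays, whatever its cause, and is not an error rate of the rule. Without noise the rule recovered between 94.4% and 96.7%, and called 0.0% of unchanged genes. Of simulated lists without a shift, 5.0% lay outside the central 95% of random lists, and 100% of lists shifted by 0.5 on the log2 scale lay above it. The simulated lists were themselves random draws, so the share without a shift follows from the design. It does not cover lists of genes that vary together. Alternatives covered the scaling between arrays, the floor, a pseudocount, the size rule, the probe sets per gene and the control array. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.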

Results

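Aortic smooth muscle cells, the contractile cells of the arterial wall, were grown for 3 days with serum and kept for 3 days without it, and then received a factor or its vehicle for 24 h. Interleukin-1b (IL-1b), an inflammatory cytokine, was given at 2.5 ng/mL and was dissolved in 10 mM acetic acid with albumin (BSA) at 0.1%, which alone made up its vehicle. PDGF-DD, a platelet-derived growth factor that signals mainly through PDGF receptor beta, was given at 30 ng/mL, and its vehicle held 0.01% BSA. Each of the 4 groups was 1 sample on 1 array, so every difference below is between single arrays, has no replicate check and carries no p-value; the number of arrays limits the precision throughout. On the IL-1b vehicle, IL-1b, PDGF-DD vehicle and PDGF-DD arrays, 60.8%, 61.5%, 59.4% and 58.3% of probe sets were above the floor.

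The vehicle arrays, neither of which received a factor, differed in genes of cell division, inflammation and contraction among others. Mki67, a marker of proliferating cells, was 10.3-fold higher on the PDGF-DD vehicle array than on the IL-1b vehicle array. The acute phase gene Orm1 was 18.5-fold higher there, the chemokine Ccl2 14.6-fold and the complement component C3 13.6-fold. Acta2 (smooth muscle alpha-actin) and Myh11 (smooth muscle myosin heavy chain) were 1.81-fold and 2.64-fold lower on it. The matrix-associated genes Crispld2 and Omd were 36.3-fold and 29.4-fold lower.

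Of 31 measured G2/M phase genes, 30 were at least 2-fold higher on the PDGF-DD vehicle array than on the IL-1b vehicle array, with a median log2 ratio of 2.48. S phase genes had a median of 1.43, with 16 of 26 at least 2-fold higher, and cholesterol and fatty acid synthesis genes 1.09, with 14 of 27. Complement and acute phase genes had a median of 2.41 (9 of 10 at least 2-fold higher), chemokines 1.26 (9 of 14) and NF-kappaB feedback and target genes 0.67 (10 of 21). The contractile genes had a median of -0.42, with 7 of 27 at least 2-fold lower, and the 10 reference genes a median of 0.10. Growth factor feedback and immediate early genes had a median of 0.63, protease inhibitors 0.68, prostanoid and nitric oxide synthesis 0.64, MHC class I antigen presentation 0.38 and vasoactive receptors -0.54, and Cd74, the invariant chain of MHC class II, was 5.53-fold higher on the PDGF-DD vehicle array. Leukocyte and macrophage markers had a median of 2.23, with 3 of 5 at least 2-fold higher. The median of this list lay outside all of 10000 random lists of the same size and level. So did those of the G2/M, S phase, cholesterol, complement, chemokine, NF-kappaB, growth factor feedback, prostanoid and contractile lists. A factor's list median therefore has to be read beside these values. Counted over all genes, 1087 of 10388 (10.5%) were at least 2-fold apart, 602 of them higher and 485 lower on the PDGF-DD vehicle array; the counts for IL-1b and PDGF-DD against their vehicles were 1236 and 904. The vehicles differ in composition, and this comparison holds that difference together with any difference between cultures, days or arrays. A spike-in control, BioC, which contains no RNA of the cells, was 2.63-fold higher on the IL-1b vehicle array than on the PDGF-DD vehicle array, and 1.13-fold and 1.26-fold apart within the IL-1b and PDGF-DD pairs. The other spike-ins, BioB, BioD and Cre, had IL-1b vehicle over PDGF-DD vehicle ratios of 0.95, 0.85 and 0.96. Within the PDGF-DD pair they were further apart, at 1.34-fold, 1.33-fold and 1.34-fold higher on the vehicle array. Within the IL-1b pair their ratios of vehicle over IL-1b were 0.995, 1.05 and 0.964. The 3'/5' intensity ratio of beta-actin, a sign of RNA quality, was 1.58 and 2.05 on the IL-1b vehicle and IL-1b arrays and 1.26 and 1.37 on the PDGF-DD vehicle and PDGF-DD arrays.

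**Figure D1:**
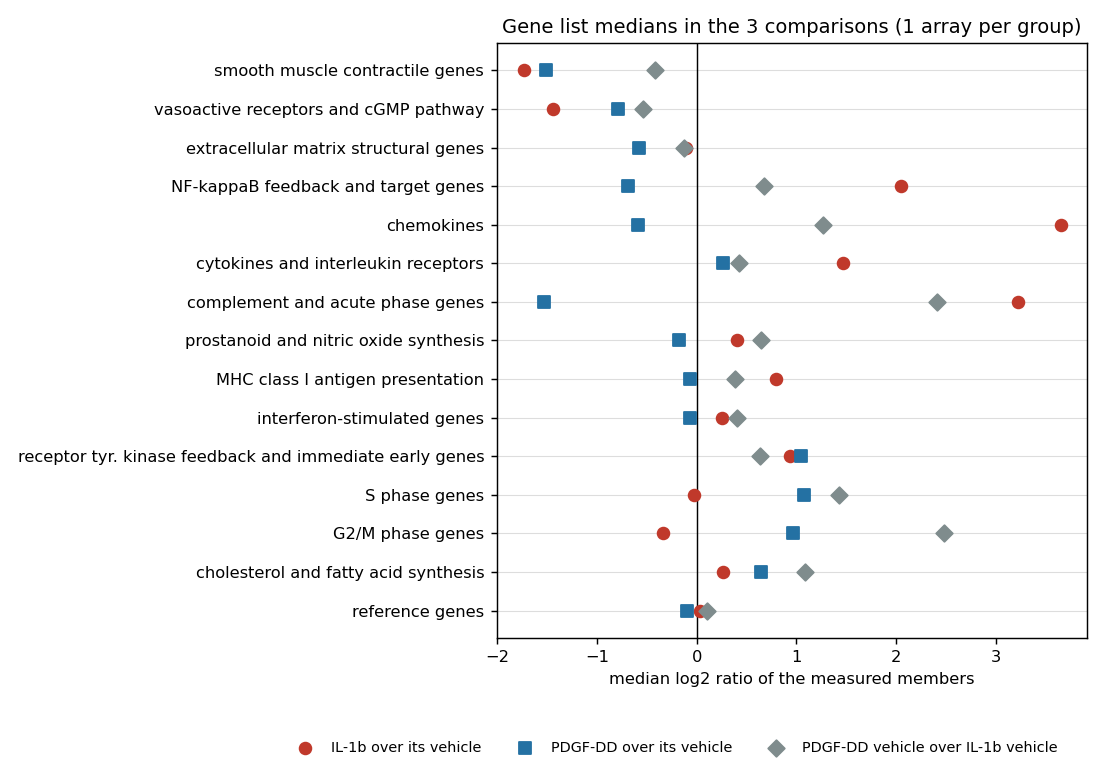
Median log2 ratio of the measured members of 15 gene lists (x axis) for IL-1b over its vehicle (circles), PDGF-DD over its vehicle (squares) and the PDGF-DD vehicle over the IL-1b vehicle (diamonds), each from single arrays. The contractile list lies at -1.73 with IL-1b and -1.51 with PDGF-DD, and the largest distance between the vehicle arrays, 2.48, is that of the G2/M list.

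The question asked of the IL-1b arrays was how the cytokine alters gene expression in these cells. With IL-1b, inflammatory genes were higher and contractile genes lower than with its vehicle. Orm1, an acute phase protein, was 244-fold higher, at an intensity of 8189 against 33.5. Pla2g2a, a secreted phospholipase that releases arachidonic acid, was at least 219-fold higher, the chemokine Cxcl6 at least 139-fold and the cytokine Il6 at least 130-fold. The log2 ratios of Orm1, Pla2g2a, Cxcl6 and Il6 were 7.93, 7.78, 7.12 and 7.02 against the IL-1b vehicle array. They were 3.73, 4.14, 6.51 and 3.03 against the PDGF-DD vehicle array. Acta2 was 3.57-fold lower (2798 against 9980), Myh11 5.53-fold lower, and Cnn1 (calponin, an actin-binding protein of the contractile apparatus) 5.33-fold lower. Against the PDGF-DD vehicle array the log2 ratios of Acta2 and Myh11 were -0.98 and -1.07, the former less than 2-fold. With its own vehicle the log2 ratio of Acta2, -1.83, was within the vehicle limit of 1.99.

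The contractile list was lower with IL-1b in 21 of 26 measured members by at least 2-fold and higher by that much in 0, with a median log2 ratio of -1.73. Tagln (transgelin) was 2.01-fold lower, Lmod1, an actin nucleator, 8.33-fold, and Synpo2, an actin-bundling protein, 11.4-fold. Myocd, the coactivator that drives contractile genes, was 5.74-fold lower, and Klf4, a transcription factor that represses them, was at least 31.8-fold higher (892 against the floor); Klf4 was also at least 15.8-fold higher on the PDGF-DD vehicle array than on the IL-1b vehicle array. Against the PDGF-DD vehicle the log2 ratios of Tagln (-0.91) and Myocd (-0.88) were also less than 2-fold. With its own vehicle the log2 ratio of Tagln, -1.01, was within the vehicle limit of 1.99. Further probe sets of Synpo2 gave log2 ratios between -1.62 and -0.50, and the other probe set of Myh11 gave -1.50, both smaller than the probe sets that stood for the genes. Striated muscle actin Acta1 was 18.3-fold lower and troponin C, Tnnc1, 20.6-fold lower. Among vasoactive receptors and the cGMP pathway, 11 of 19 genes were at least 2-fold lower and 4 higher (median -1.44), including Rgs5 (13.8-fold lower) and Npr3, a natriuretic peptide clearance receptor (11.1-fold lower). Against the PDGF-DD vehicle the vasoactive median was -0.49. Rgs2, a regulator of G protein signalling, went the other way at 23.8-fold higher. Its log2 ratio was 4.58 against the IL-1b vehicle and 1.08 against the PDGF-DD vehicle.

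NF-kappaB feedback and target genes were at least 2-fold higher in 15 of 22 measured members with IL-1b and lower in 0, with a median log2 ratio of 2.05. Map3k8 was at least 50.3-fold higher, Zc3h12a, an RNase that degrades inflammatory transcripts, 19.6-fold, Irak3, an inhibitor of IL-1 receptor signalling, 13.3-fold, and the adhesion molecule Vcam1 5.97-fold (a log2 ratio of 0.57 against the PDGF-DD vehicle, less than 2-fold). Chemokines had a median of 3.65, with 13 of 17 at least 2-fold higher; against the PDGF-DD vehicle it was 1.11, with 9 of 18 higher and 2 lower. Cxcl2 was at least 130-fold higher, Ccl5 at least 87.0-fold and Ccl20 at least 53.0-fold. Their log2 ratios against the PDGF-DD vehicle were at least 7.03, at least 6.44 and 2.42. Cxcl13 was the exception, at 20.3-fold lower. Among cytokines and interleukin receptors, 11 of 17 were at least 2-fold higher (median 1.47), among them the colony-stimulating factors Csf3 (at least 67.1-fold) and Csf2 (at least 22.1-fold) and the receptor Il1rl1 (at least 22.9-fold). Il1r1, the receptor of IL-1b itself, was 19.3-fold higher; its other probe sets gave log2 ratios between 2.09 and 2.30. Complement and acute phase genes had a median of 3.22, with 11 of 12 at least 2-fold higher, led by Orm1, C3 (19.5-fold) and the lipopolysaccharide-binding protein Lbp (18.4-fold); against the PDGF-DD vehicle the log2 ratio of C3 was 0.52, less than 2-fold.

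In prostanoid and nitric oxide synthesis, 8 of 17 genes were at least 2-fold higher (median 0.41, and 0.64 against the PDGF-DD vehicle). They included Ptges, a prostaglandin E synthase (at least 11.9-fold), cyclooxygenase Ptgs2 (6.24-fold), Ass1, which makes argininosuccinate for arginine supply (at least 216-fold), and Arg1, an arginase (8.57-fold). The other probe set of Ptges gave a log2 ratio of 1.94, smaller than the one that stood for the gene. The glucocorticoid-activating enzyme Hsd11b1 was 54.7-fold higher, the glutathione transferase Mgst1 29.0-fold and the ligand Wnt4 23.9-fold. Hsd11b1, Mgst1 and Wnt4 had log2 ratios of 5.77, 4.86 and 4.58 against the IL-1b vehicle. These were 2.48, 4.61 and 3.54 against the PDGF-DD vehicle. Antigen presentation genes of MHC class I had a median of 0.79, with 5 of 15 at least 2-fold higher, and interferon-stimulated genes a median of 0.26, with 2 of 21. Against the PDGF-DD vehicle these medians were 0.29, with 0 of 15 higher, and -0.07, with 0 of 21 higher. Cd74 was 32.0-fold higher, and the class II genes RT1-Da and RT1-Bb were 20.5-fold and 27.9-fold higher.

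Proteases and matrix genes went both ways with IL-1b. Of 17 matrix metalloproteinases and ADAMTS proteases, 6 were at least 2-fold higher and 4 lower (median 0.23, and 0.86 against the PDGF-DD vehicle). Stromelysin Mmp3 was at least 19.5-fold higher, collagenase Mmp13 at least 10.1-fold and gelatinase Mmp2 4.01-fold, and Mmp11 was 7.15-fold lower (a log2 ratio of -0.83 against the PDGF-DD vehicle); another probe set of Mmp2 gave 0.70. Among protease inhibitors and plasminogen system genes, 5 of 10 were at least 2-fold higher (median 0.74), but against the PDGF-DD vehicle the median was -0.16, with 2 of 10 higher. The plasminogen activator Plat was 17.7-fold higher and the inhibitor Timp1 3.82-fold, with Timp3 3.55-fold lower; against the PDGF-DD vehicle the log2 ratios of Timp1 and Timp3 were 0.35 and -0.91, both less than 2-fold. Of 43 structural matrix genes, 8 were at least 2-fold higher and 8 lower (median -0.10), and against the PDGF-DD vehicle 5 were higher and 4 lower (median -0.02); Vcan (versican) was 9.54-fold higher and Ogn (osteoglycin) 10.1-fold lower. Other probe sets of Vcan gave log2 ratios between 0.06 and 3.78, and against the PDGF-DD vehicle that of Ogn was -0.31. The fibrillar collagens Col1a1 and Col3a1 were 1.07-fold and 1.22-fold lower, with log2 ratios that turned to 0.24 and 0.08 against the PDGF-DD vehicle. Spon2 and Tinagl1, which encode extracellular proteins, were 19.2-fold and 19.0-fold lower.

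The values of cell cycle genes with IL-1b depended on the vehicle. Against its own vehicle, S phase genes had a median of -0.02, with 1 of 26 at least 2-fold higher and 1 lower, and G2/M genes a median of -0.34, with 2 of 30 lower, Kif23 (4.34-fold) and Nuf2 (2.04-fold). Against the PDGF-DD vehicle the S phase median was -1.19, with 15 of 26 lower, and the G2/M median -2.72, with 31 of 31 lower. Among cell cycle inhibitors and G1 cyclins 6 of 17 were at least 2-fold higher and 2 lower (median -0.07), including cyclin D1, Ccnd1 (10.5-fold higher), and the inhibitor Cdkn2a (3.71-fold higher); against the PDGF-DD vehicle the list median was 0.25, with 5 of 18 higher and 2 lower, and the log2 ratio of Ccnd1 was 0.85, less than 2-fold. Receptor tyrosine kinase feedback and immediate early genes were at least 2-fold higher in 11 of 24 and lower in 3 (median 0.93), with the MAP kinase phosphatase Dusp6 6.06-fold higher, and between 0.94 and 4.04 on the log2 scale by its other probe sets. PDGF and TGF-beta family genes had a median of 0.03, with 6 of 29 at least 2-fold higher and 4 lower. Pdgfra was 4.48-fold higher, Bmp6 20.4-fold higher and Tgfb3 4.38-fold lower, and Pdgfrb was 1.14-fold lower. Other probe sets of Bmp6 gave smaller log2 ratios, between 2.03 and 3.44. Against the PDGF-DD vehicle the log2 ratio of Pdgfra was 0.73, less than 2-fold, and that of Pdgfrb turned to 0.37. Cholesterol and fatty acid synthesis genes had a median of 0.27, with the desaturase Fads1 4.64-fold lower; against the PDGF-DD vehicle the median was -0.89, with 11 of 27 lower. Reference genes had a median of 0.03.

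Counted over all genes, 657 of 10678 were at least 2-fold higher with IL-1b and 579 lower, 11.6% together. Of these genes, 329 higher and 189 lower also met the rule against the PDGF-DD vehicle array. Among 348 of them with another measured probe set, 25 had a probe set of the other sign, 2 of them at least 2-fold. Several list medians lay outside all of 10000 random lists of the same size and level. They were those of the contractile, vasoactive, NF-kappaB, chemokine, cytokine, complement, MHC class I, growth factor feedback and G2/M lists. Medians of the oxidative stress, endoplasmic reticulum stress and leukocyte lists, given further below, did so too. Against the PDGF-DD vehicle the contractile median was -1.13, with 14 of 25 lower, the NF-kappaB median 1.08, with 11 of 22 higher, the cytokine median 1.38, with 11 of 17 higher, and the complement median 0.54, with 5 of 12 higher and 1 lower.

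**Figure D2:**
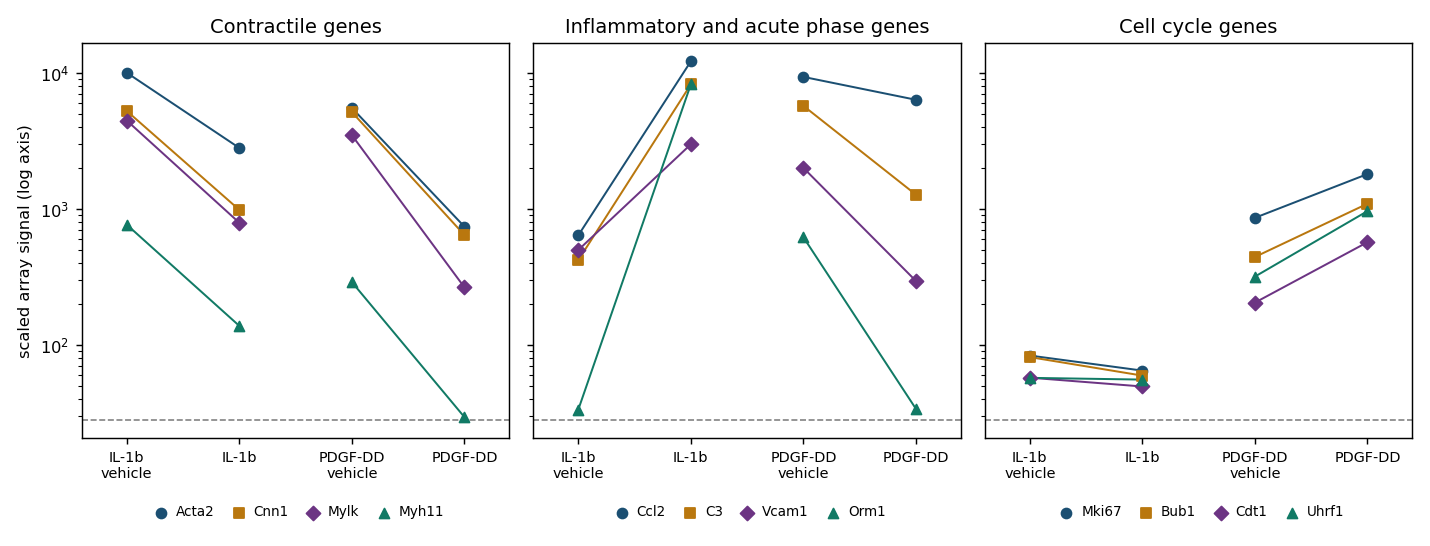
Scaled intensity (y axis, log scale) of 12 genes on the 4 arrays (x axis), 1 point per array, with lines joining each factor to its vehicle and a dashed line at the floor of 28.1. Acta2 lies at 9980, 2798, 5504 and 739 from left to right, and Orm1 at 33.5, 8189, 618 and 34.0.

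The PDGF-DD arrays addressed the same question for the growth factor. With PDGF-DD, contractile genes were lower and genes of DNA replication and growth factor feedback higher than with its vehicle. Acta2 was 7.44-fold lower (739 against 5504), Myh11 at least 9.81-fold lower (29.5, beside the floor) and myosin light chain kinase, Mylk, 13.1-fold lower; Cnn1 had an intensity of 642 against 5134. Fosl1, a transcription factor of the AP-1 family, was 9.67-fold higher and Dusp6 6.29-fold higher. Cyclin D1, Ccnd1, was 3.50-fold higher and Mki67 2.10-fold higher. The log2 ratios of Ccnd1 (1.81) and Myh11 (-3.29) were within their vehicle limits of 2.08 and 3.41.

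Contractile genes were at least 2-fold lower in 18 of 25 measured members and higher in 0, with a median log2 ratio of -1.51; against the IL-1b vehicle 24 of 26 were lower (median -2.19). Actg2 was at least 17.8-fold lower, Myl9 8.57-fold and Tagln 2.79-fold (a log2 ratio of -1.48, within its vehicle limit of 1.99). Myocd was 1.75-fold lower and Klf4 2.89-fold higher. The intensity of Myocd was 169 with PDGF-DD and 161 with IL-1b, and its vehicle arrays differed 3.13-fold, with 296 for PDGF-DD and 924 for IL-1b. The other probe set of Myh11 gave -0.44. Beyond the list, Fbxl22, a muscle F-box protein, was at least 42.5-fold lower, at an intensity of 28.5 beside the floor, Acta1 30.1-fold, the collagen-binding integrin Itga11 16.6-fold and Tnnc1 15.8-fold. Vasoactive receptors and the cGMP pathway had a median of -0.78, with 7 of 17 at least 2-fold lower and 1 higher, and of -1.71 against the IL-1b vehicle. Rgs4, a regulator of G protein signalling, was at least 85.0-fold lower and Npr3 7.88-fold lower.

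S phase genes were at least 2-fold higher in 19 of 26 members with PDGF-DD (median 1.08), among them the helicase Hells (an intensity of 410 against 103), Uhrf1 (3.03-fold) and the replication licensing factor Cdt1 (2.78-fold). G2/M genes had a median of 0.96, with 15 of 31 at least 2-fold higher, including Ttk (2.98-fold) and Bub1 (2.46-fold), both kinases of the spindle checkpoint. Against the IL-1b vehicle the S phase and G2/M medians were 2.59 and 3.54. These genes were already higher on the PDGF-DD vehicle array than on the IL-1b vehicle array, by 7.40-fold for Ttk and 5.44-fold for Bub1. Among cell cycle inhibitors and G1 cyclins, 2 of 16 were at least 2-fold higher, Ccnd1 and the inhibitor Cdkn2b (2.86-fold), with a list median of 0.14; against the IL-1b vehicle 5 of 18 were higher and 4 lower (median -0.14). Receptor tyrosine kinase feedback and immediate early genes were at least 2-fold higher in 14 of 26 members and lower in 2 (median 1.04). Dusp5 was at least 7.64-fold higher, Jun 4.53-fold and Egr1 4.13-fold, and Spry1, an inhibitor of receptor tyrosine kinase signalling, was 8.35-fold lower. Cholesterol and fatty acid synthesis genes had a median of 0.64, with 7 of 27 at least 2-fold higher and 0 lower, such as Insig1 (2.39-fold) and Msmo1 (2.22-fold), and one of 1.80 against the IL-1b vehicle.

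Structural matrix genes were at least 2-fold lower in 14 of 42 members with PDGF-DD and higher in 2 (median -0.58), and against the IL-1b vehicle lower in 18 of 43 and higher in 8 (median -0.71). Col14a1 was 8.64-fold lower and elastin, Eln, 5.72-fold, and Col1a1 and Col3a1 were 1.51-fold and 1.29-fold lower. Matrix metalloproteinases and ADAMTS proteases had a median of -0.35, with 5 of 13 at least 2-fold lower and Mmp16 4.32-fold higher (a log2 ratio of 0.82 against the IL-1b vehicle). Protease inhibitors and plasminogen system genes had a median of -0.22, with 2 of 10 at least 2-fold higher, Serpinb2 (at least 2.81-fold) and the urokinase receptor Plaur (2.03-fold). Against the IL-1b vehicle the protease median was -0.75 and the protease inhibitor median 1.00, with 5 of 10 higher and 2 lower. PDGF and TGF-beta family genes had a median of -0.46, with 2 of 27 at least 2-fold higher and 3 lower, and against the IL-1b vehicle 4 of 29 higher and 6 lower (median -0.41). Pdgfrb was 1.82-fold lower, Pdgfra 1.63-fold lower and Id1 3.44-fold higher; the log2 ratio of Pdgfra turned to 0.74 against the IL-1b vehicle. Palldl1 was 18.0-fold higher, Hmga1, a chromatin protein, 6.79-fold and Esm1, a secreted proteoglycan, 5.44-fold.

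Complement and acute phase genes were at least 2-fold lower with PDGF-DD in 8 of 10 members (median -1.53), with Orm1 18.2-fold lower, Hp (haptoglobin) 7.84-fold and C3 4.49-fold. NF-kappaB feedback and target genes had a median of -0.69, with 7 of 21 at least 2-fold lower and 1, Ripk2, 5.30-fold higher; Vcam1 was 6.77-fold lower (a log2 ratio of -0.75 against the IL-1b vehicle). Chemokines had a median of -0.59, with 5 of 14 at least 2-fold lower and 0 higher. These directions depended on the vehicle. Against the IL-1b vehicle array the medians of PDGF-DD were 0.02 for complement and acute phase genes, 0.39 for NF-kappaB genes and 1.69 for chemokines. The complement median, over 9 genes, was the value of Orm1. At 33.5 on the IL-1b vehicle array, beside the floor, Orm1 could not be 2-fold lower. Cytokines and interleukin receptors had a median of 0.26, with 3 of 13 at least 2-fold higher and 2 lower; the alarmin Il33 was 7.23-fold higher and Il11 at least 4.77-fold, though against the IL-1b vehicle the log2 ratio of Il33 was 0.78, less than 2-fold. Prostanoid and nitric oxide synthesis genes had a median of -0.18, with 2 of 15 at least 2-fold higher and 3 lower, and Ptgs2 was 2.20-fold higher. MHC class I antigen presentation (0 of 15 at least 2-fold apart) and interferon-stimulated genes (1 of 21) both had a median of -0.07, and the reference genes one of -0.10, which was 0.06 after quantile normalization; for MHC class I it was 0.02 with the scaling as deposited. Against the IL-1b vehicle the medians were 0.63 for cytokines, 0.71 for prostanoid and nitric oxide synthesis, 0.50 for MHC class I, 0.12 for interferon-stimulated and 0.06 for reference genes.

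Over all genes, 430 of 10141 were at least 2-fold higher with PDGF-DD and 474 lower, 8.91% together, and 344 and 322 of these also met the rule against the IL-1b vehicle array. Against that vehicle array, PDGF-DD had 1002 genes higher and 1074 lower. Medians of the contractile, vasoactive, NF-kappaB, chemokine, complement, matrix, S phase, G2/M, growth factor feedback and cholesterol lists lay outside all of 10000 random lists. So did that of the leukocyte list, over 4 measured genes. Among 233 called genes with another measured probe set, 12 had a probe set of the other sign, 0 of them at least 2-fold.

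Markers of endothelial cells, leukocytes, adipocytes and Schwann cells were mostly at the floor, while most fibroblast markers were above it. Of 24 leukocyte and macrophage markers 9 were above it in the IL-1b comparison, with a median of 0.57 (1.35 over 8 against the PDGF-DD vehicle); the 4 that were at least 2-fold higher were Cd74, RT1-Da, RT1-Ba and Lyz2 (lysozyme, at least 46.5-fold). RT1-Ba was 31.4-fold higher by its strongest probe set, while other probe sets of the gene gave log2 ratios between -1.45 and 0.53. In the PDGF-DD comparison 4 of these markers were measured (median -2.36), with 3 at least 2-fold lower; against the IL-1b vehicle the median was -0.16, with 0 of 5 lower. Fibroblast and adventitial markers had a median of 0.55 with IL-1b (5 of 12 at least 2-fold higher, 1 lower) and -0.69 with PDGF-DD (3 of 9 lower); Dpt (dermatopontin) was at least 45.9-fold higher with IL-1b. For endothelial markers 3 and 4 of 15 genes were measured, with medians of -0.51 and 0.14; Flt1, a VEGF receptor, was 6.15-fold higher with PDGF-DD. Of the adipocyte and Schwann cell markers, 1 was measured, Mbp, at least 3.43-fold higher with IL-1b. Genes restricted to other organs had medians of -0.02 over 6 genes with IL-1b and -0.50 over 4 with PDGF-DD.

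Genes lower with both factors were the largest shared group, and the contractile genes were among them. Myh11, Cnn1, Mylk, Acta1, Tnnc1, Itga11 and Fbxl22 were at least 2-fold lower with each factor. Vldlr, a lipoprotein receptor, was 4.60-fold lower with IL-1b and 4.94-fold lower with PDGF-DD. Higher with both were Slc7a11, a cystine transporter (10.3-fold and 6.63-fold), Fosl1 (at least 5.52-fold and 9.67-fold) and Ripk2 (9.24-fold and 5.30-fold). The median difference of the log2 ratios, IL-1b minus PDGF-DD, was 0.02 for the contractile list, 4.11 for complement and acute phase genes, 3.67 for chemokines, 2.42 for NF-kappaB genes, -1.18 for S phase genes and -1.25 for G2/M genes.

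Among 9935 genes measured in both comparisons, 167 were at least 2-fold lower with both, where independent lists would share 25.2, and 78 were higher with both, where independent lists would share 24.1. In opposite directions, 89 were higher with IL-1b and lower with PDGF-DD (28.3 for independent lists), and 16 were lower with IL-1b and higher with PDGF-DD (21.4). The ratios of the factors share no array. Across 10884 genes, which are not independent replicates, the log2 ratios correlated with Pearson's r of 0.16 and Spearman's rho of 0.19; with the vehicle arrays exchanged Pearson's r was -0.18. Genes with a higher ratio with IL-1b included Orm1 (a difference of 12.12 on the log2 scale), Pla2g2a (at least 10.78) and Ccl20 (at least 9.03). With the vehicle arrays exchanged the log2 ratios of Orm1 were 3.73 with IL-1b and 0.02 with PDGF-DD. Palldl1, higher with PDGF-DD, was at the floor on both IL-1b arrays. Crispld2 was 29.0-fold lower with IL-1b than with its vehicle, but its log2 ratio against the PDGF-DD vehicle was 0.33.

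**Figure D3:**
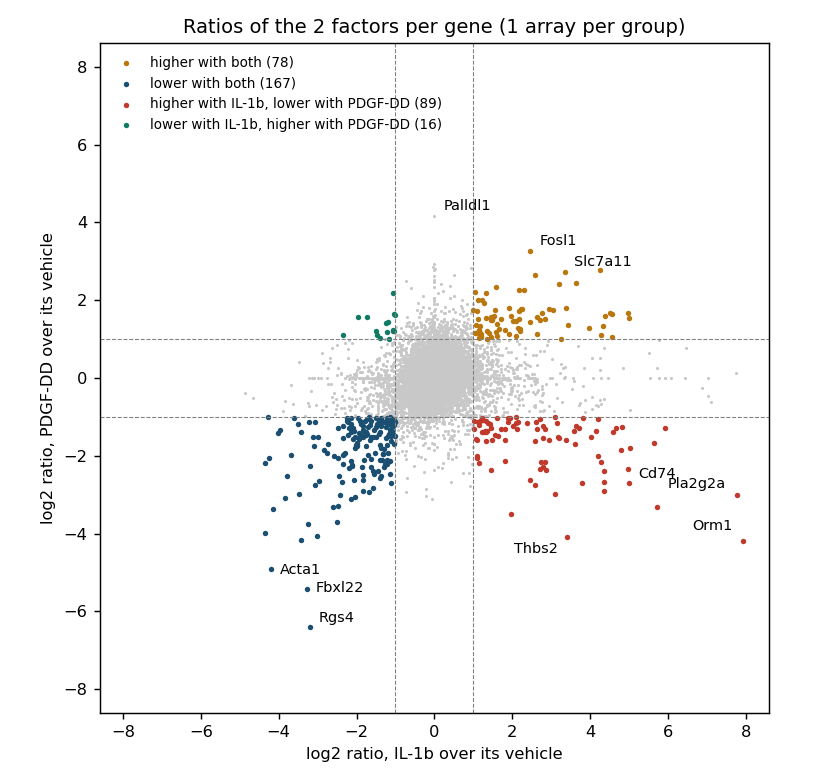
Log2 ratio of IL-1b over its vehicle (x axis) against that of PDGF-DD over its vehicle (y axis) for 10884 genes above the floor on at least 1 array, with dashed lines at a 2-fold difference. Colours mark the 78 genes higher with both, 167 lower with both, 89 higher with IL-1b and lower with PDGF-DD, and 16 the other way.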

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

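All tests in this part were chosen after the results they measure had been seen. Several genes were at least 2-fold apart in opposite directions with the factors, and these differences between the factors were not tested, since each group is 1 array. On the log2 scale, the ratio with IL-1b minus the ratio with PDGF-DD was 12.12 for Orm1, at least 10.78 for Pla2g2a, at least 9.03 for Ccl20, 7.70 for Cd74, 7.49 for Thbs2, 7.25 for Bmp6, at least 6.51 for the MHC class II gene RT1-Db1 and 6.08 for Hp. Against the IL-1b vehicle array 0 of these 8 genes were at least 2-fold lower with PDGF-DD, with log2 ratios between -0.69 (Bmp6) and 0.64 (Pla2g2a). That count was partly fixed in advance. Pla2g2a and Ccl20 were at the floor of 28.1 on that array, and Orm1 (33.5) and RT1-Db1 (41.9) beside it. None of these could be 2-fold lower there. The 8 genes were also picked for their opposite ratios, so the count cannot decide whether the directions rest on the vehicle. Gene lists whose medians had opposite signs, each outside the central 95% of random lists with both factors, were also not tested. The median difference was 4.11 for complement and acute phase genes, 3.67 for chemokines and 2.42 for NF-kappaB genes. It was 0.57 for leukocyte and macrophage markers, 0.50 for fibroblast and adventitial markers and -1.25 for G2/M genes. The leukocyte medians were over unlike sets, 9 genes with IL-1b and 4 with PDGF-DD. The leukocyte difference equals the IL-1b median and does not reflect the lower PDGF-DD median. In data that the comparisons of the groups do not use, the spike-in control BioC was 2.63-fold higher on the IL-1b vehicle array than on the PDGF-DD vehicle array. The same ratio was 0.95 for BioB, 0.85 for BioD and 0.96 for Cre. Among probe sets without a single gene name, 616 of 5356 above the floor were at least 2-fold apart between IL-1b and its vehicle (11.5%), 388 of 4839 between PDGF-DD and its vehicle (8.02%) and 493 of 5175 between the vehicle arrays (9.53%).

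The vehicle arrays differed in G2/M genes by a median log2 ratio of 2.48, and in 1087 genes by at least 2-fold. A difference in scale factor between the arrays is argued against, because it would move all genes alike. The median log2 ratio over all genes above the floor on at least 1 array was -0.02, against 2.48 for the G2/M genes. That the median over all genes lay near 0 follows from the scaling and is no evidence by itself. The lowest G2/M median under the other scalings was 2.48, but with scale factors of 1.03 and 1.01 the linear scalings could hardly move it. Exchanged labels of the vehicle arrays stay open: 2076 genes were at least 2-fold apart between PDGF-DD and the IL-1b vehicle array and 904 from its own, but for IL-1b the counts were 1095 and 1236, and BioC, 1.13-fold and 1.26-fold apart within the labelled pairs, speaks against exchanged arrays only if each pair was hybridized together, and not against RNA exchanged before. A separate culture or hybridization batch for each pair also stays open, and the spike-ins are divided on it. BioC differed 2.63-fold between the vehicle arrays, while BioB, BioD and Cre had ratios of 0.95, 0.85 and 0.96 (IL-1b vehicle over PDGF-DD vehicle). Within the PDGF-DD pair BioB, BioC, BioD and Cre were between 1.26-fold and 1.34-fold higher on the vehicle array. Spike-ins do not say whether the cultures differed. Each vehicle was measured on 1 array, so a batch, the growth state of the culture and the composition of the vehicle cannot be told apart.

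Cd74, RT1-Da, RT1-Ba and Lyz2, all genes of antigen-presenting cells and macrophages, reached intensities of 3379, 1919, 1210 and 1305 on the IL-1b array. Leukocytes carried into the culture would bring their other abundant transcripts as well. Of the 20 other leukocyte and macrophage markers, 15 were at the floor on both arrays of the pair. The largest log2 ratio among the 5 above it was 0.57, and the strongest of them reached 1333 on the IL-1b array. The 4 genes set aside were the only list members at least 2-fold higher, so the rest had to lie below 2-fold. That ratio therefore cannot decide whether such cells were the source. Whether each probe set of the 20 markers responds to its transcript was not tested. Leukocytes in the culture and expression of the 4 genes by the cultured cells themselves both stay open as hypotheses.

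NF-kappaB and complement genes were lower on the PDGF-DD array than on its vehicle array, with medians of -0.69 and -1.53. Against the IL-1b vehicle array the medians were 0.39 and 0.02, so the lower values could stem from a raised level of these genes on the PDGF-DD vehicle array. The complement median there is the value of Orm1, which at 33.5 lay beside the floor and could not be 2-fold lower. A repression by PDGF-DD of genes that are active in that culture stays open and was not tested. Both vehicle arrays would have to be replicated to separate these.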

How the results depend on the processing

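The scaling as deposited was added after the data had been seen. Contractile genes kept a negative median with both factors under every alternative that gave a list median, between -1.13 and -2.19 in the settings that moved it. Over the alternatives, 60 gene counts stayed within 1.5 times and 21 did not; 29 of 557 list medians changed sign, 7 of them of lists outside the central 95% of random lists, and so did 48 of 2150 values of genes named in the text, 12 of them of genes at least 2-fold apart. With the other vehicle array there were 16 and 30 of these sign changes, and with settings other than the vehicle 5 and 3. Quantile normalization, scaling to the median above the floor and the scaling as deposited turned no list outside the central 95% and no named gene at least 2-fold apart. No paired analysis was possible because each group is 1 array, and for the same reason no array could be left out. Intensity limits what can be seen: about 40% of values lie at the floor, and folds from it are lower bounds.

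With the floor at the 25th percentile, 1017 genes were at least 2-fold higher with IL-1b and the NF-kappaB median with IL-1b was 2.53. With the floor at the 60th percentile, where fewer genes are counted, 410 were higher and 383 lower with IL-1b, 306 lower with PDGF-DD, 633 apart between the vehicle arrays, 42 higher and 108 lower with both factors; the contractile medians were -1.58 with IL-1b and -1.37 with PDGF-DD, and the NF-kappaB median with IL-1b 1.52. That median was 1.48 with the mean of all probe sets and 2.58 with shared probe sets left out, and the G2/M median with IL-1b was -0.23 with a pseudocount; the cause was not tested. A 3-fold rule, stricter by construction, gave 323 higher and 253 lower with IL-1b, 88 and 171 with PDGF-DD, 441 between the vehicle arrays, and 22 higher and 57 lower with both. Requiring 2-fold against both vehicle arrays gave 329 higher and 189 lower with IL-1b, and 41 higher and 93 lower with both.

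Against the other vehicle array, 1002 genes were higher and 1074 lower with PDGF-DD, and the correlation of the log2 ratios was -0.18. The medians with IL-1b and PDGF-DD were -1.13 and -2.19 for contractile, 1.08 and 0.39 for NF-kappaB, -1.19 and 2.59 for S phase and -2.72 and 3.54 for G2/M genes. They were 1.69 for chemokines and 0.0197 for complement genes with PDGF-DD, and -0.16 for protease inhibitors and -0.89 for cholesterol synthesis with IL-1b. Genes at least 2-fold apart that changed sign had log2 ratios with PDGF-DD of 0.51 (Arg1), 1.60 (C3), 1.37 (Map3k8), 0.0197 (Orm1), 0.64 (Pla2g2a), 0.37 (RT1-Ba) and 0.54 (Thbs2), and with IL-1b of 0.33 (Crispld2), 0.31 (Eln), -0.00601 (Id1), 0.22 (Omd) and -1.20 (Thbs2). Against the mean of both vehicle arrays, 662 genes were higher with PDGF-DD, and the medians with IL-1b and PDGF-DD were -1.41 and -1.91 for contractile, 1.32 and -0.15 for NF-kappaB, -0.57 and 1.79 for S phase and -1.60 and 2.28 for G2/M genes, 0.45 for chemokines with PDGF-DD and -0.36 for cholesterol synthesis with IL-1b. These values follow the distance between the vehicle arrays, whose cause was not tested.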

Other observations

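No test was run for the lists in this part, whose values stand without an explanation; the lists were chosen before and the genes named follow the same rule. Genes of the oxidative stress response had a median log2 ratio of 0.64 with IL-1b, with 8 of 19 at least 2-fold higher, 0 lower and 11 within 2-fold, and against the PDGF-DD vehicle 3 of 19 were higher. The metallothionein Mt2A was 4.52-fold higher and the quinone reductase Nqo1 4.25-fold, but against the PDGF-DD vehicle their log2 ratios were 0.82 and 0.43, less than 2-fold. With PDGF-DD their median was 0.16, with 3 of 19 higher and 1 lower, and between the vehicle arrays it was 0.17. Endoplasmic reticulum stress genes had medians of 0.56 with IL-1b (4 of 21 at least 2-fold higher, 1 lower) and 0.33 with PDGF-DD (3 of 21 higher, 1 lower), with the chaperone cofactor Sdf2l1 4.39-fold higher with IL-1b. Lipid uptake and efflux genes had medians of 0.39 with IL-1b (3 of 15 higher, 2 lower) and -0.24 with PDGF-DD (2 of 12 higher, 1 lower), and the fatty acid binding protein Fabp5 was 10.7-fold and 2.57-fold higher. Glycolysis genes had medians of 0.22 (1 of 16 higher) and 0.02 (2 of 17 higher, 1 lower), with hexokinase Hk2 4.70-fold higher with PDGF-DD. Osteochondrogenic genes had medians of -0.10 over 8 genes and 0.06 over 5; Enpp1, which makes pyrophosphate, a mineralization inhibitor, was 3.44-fold higher with PDGF-DD. Against the other vehicle array the medians with IL-1b and PDGF-DD were 0.43 and 0.53 for oxidative stress, 0.24 and 0.72 for endoplasmic reticulum stress, 0.34 and -0.14 for lipid uptake, -0.06 and 0.39 for glycolysis and 0.22 and -0.18 for osteochondrogenic genes.

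The arrays of a pair were the most alike with PDGF-DD: the Pearson correlation of log2 intensities was 0.972 between PDGF-DD and its vehicle, 0.952 between IL-1b and its vehicle and 0.963 between the vehicle arrays. IL-1b and the PDGF-DD vehicle correlated at 0.962, above IL-1b and its own vehicle. The lowest value, 0.930, was that of PDGF-DD and the IL-1b vehicle. The 3'/5' intensity ratio of GAPDH lay between 1.07 and 1.27 on the 4 arrays.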
